A study of Homo sapiens with 24 samples.

How the data were processed

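RNA from 24 samples of the AML cell lines KG-1, HL-60, MOLM-14 and U937 was profiled on Affymetrix high-throughput human U133 arrays of the A set, in 8 groups of 3. Cells received DMSO or 4 µM R406 for 24 h. The treatment protocol gives the dose in µM, which is used here, while the series design text gives it in mM. Total RNA had been isolated with Qiagen RNeasy Mini columns and labelled with biotin. The deposited values are probe set intensities that the authors made with RMA (robust multi-array average) per the labels, without a stated version. Background correction, quantile normalization and a summary per probe set are the usual steps of RMA. The range and medians of the values place the intensities on a linear scale, so log2 of the value plus 1 was used for all tests. Detection calls, scan dates and batches were not used here. Samples were grouped by cell line and treatment as the labels give them. The labels do not say that the replicate numbers pair the samples, so no pairing was used.

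Of 22277 probe sets, 62 controls, 568 with several gene symbols and 1923 with none listed were set aside. For each of the 12165 genes left, the probe set with the highest mean over all 24 arrays stood for the gene. More than 1 probe set was present for 4505 genes, and 5111 genes were represented by a probe set that can bind transcripts of related genes. No filter on dim genes was applied. The genome build behind the annotation is not named, so no positions are given.

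One linear model with a mean for each of the 8 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual degrees of freedom, prior degrees of freedom 5.47). R406 minus DMSO was tested in each line and as the equal-weight mean of the 4 lines. The difference of the R406 effect between lines, and the difference between the DMSO groups, were tested with moderated F tests. Adjusted p values are Benjamini-Hochberg values over all genes, and a gene was called at an adjusted p under 0.05. The 3' to 5' ratios of ACTB and GAPDH control probe sets were compared with exact permutation tests.

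The 29 gene lists were SYK and ITAM signalling, integrins and adhesion, ERK output and feedback, STAT5 targets, MYC and ribosome biogenesis, DNA replication and E2F, mitosis, p53 targets, BCL2 family, monocyte and macrophage differentiation, granulocyte differentiation, primary granule proteins, stem and progenitor and HOXA, aryl hydrocarbon receptor targets, integrated stress response ATF4, unfolded protein response, cholesterol biosynthesis, glycolysis and hypoxia, interferon response, NF-kB and inflammatory cytokines, MHC class II, lysosome, oxidative phosphorylation, cytosolic ribosomal proteins, erythroid markers, megakaryocyte markers, B cell markers, T and NK cell markers, and fibroblast and epithelial markers. Of 529 distinct members, 468 were measured, and the others were not analysed here. Among these others were HOXA3, HOXA5, HOXA6, HOXA7, HOXA9 and HOXA10. The stem and progenitor and HOXA list was therefore tested without any HOXA gene. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The correlation was also estimated for each list, and the text gives that p where it ended a call. Of the calls, 11 of 16 in MOLM-14, 8 of 12 in U937, 9 of 13 in HL-60, 11 of 16 in KG-1 and 9 of 17 for the mean held with it. Where KG-1 R406 replicate 2, left out as well, changed that outcome, the text gives this p too. A further list of histone genes was added after the fold changes were seen.

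The main tests, the 29 lists, the rule for named genes and the alternatives below were set before the data were examined. An estimated correlation with KG-1 R406 replicate 2 left out, and leave-outs for the genes called the same way in all 4 lines, were added after results were seen. In each line the rule takes the 12 highest and 12 lowest log2 fold changes among called genes whose 3 R406 arrays all lie beyond all 3 DMSO arrays. For the mean effect it takes the 12 highest and 12 lowest of the called genes with the same sign in all 4 lines. For the difference between lines it takes the 12 called genes with the widest range, and for the DMSO groups the 5 genes of each line furthest above the other 3 lines. It adds SYK, ITGB3, ITGAV, FLT3, MYC, DUSP6, CYP1A1, CDKN1A, CD14, ITGAM and HOXA9, and up to 4 members of each list with the smallest p. The text gives a part of these genes.

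The model was tested on simulated data with known changes in 200 genes a line. It recovered 37.3% to 46.3% of changes of 1.25-fold, 85.1% to 95.5% of 1.5-fold and 97.0% to 100% of 2-fold, and 3.66% to 7.23% of calls were false. The simulated noise was independent between genes, with the same spread in all groups, and few genes changed. These rates therefore need not hold for the measured data. Alternatives tried were repeated quantile normalization, median centring, the dimmest 33.3% of genes left out, the mean of the probe sets of a gene, a pseudocount of 16, a trended robust prior, a 1.5-fold minimum, a block for the replicate number, the 6 arrays of a line alone, camera with an estimated correlation, the rotation test fry, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.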

Results

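Gene expression was measured on 24 one-colour Affymetrix arrays in 4 human acute myeloid leukemia (AML) cell lines. MOLM-14 is a monocytic line with an MLL-AF9 fusion and an internal tandem duplication in the receptor kinase FLT3. U937 is a monocytic line, HL-60 a promyelocytic line and KG-1 an early myeloblast line. Each line was treated for 24 h with 4 µM R406 or with the solvent dimethyl sulfoxide (DMSO), with 3 arrays in each of the 8 groups. R406 is the active form of fostamatinib and inhibits the tyrosine kinase SYK, along with other kinases. SYK relays signals from immune receptors and integrins, and the series title concerns a dependence of leukemia cells on integrin beta 3 signalling. The comparisons show which transcripts differed between R406 and DMSO in each line, in the mean over the lines, and between lines.

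The deposited intensities ran from 3.41 to 12686, with array medians between 19.1 and 21.4. The number of arrays limits the precision. Intensities below are the mean ± SD of n = 3 arrays. Log2 fold changes are R406 minus DMSO on log2 of the intensity plus 1, from 3 against 3 arrays, and they understate changes of dim genes. They are given ± SE from 1 variance per gene shared by all 8 groups, so a gene has the same SE in each line. This SE can understate the spread of a single group. For H2AC6 it was 0.17 in MOLM-14 and in KG-1, with R406 intensities of 1544 ± 23.3 and 1113 ± 447. The labels do not say whether the 3 arrays of a group come from separate cultures, so the p-values measure the spread between these samples, and that spread can be technical. Each gene named for a line had all 3 of its R406 arrays beyond all 3 of its DMSO arrays, apart from members of gene lists and of 10 genes chosen for their place in the study before the data were examined. For gene lists, the brackets hold the median log2 fold change of the members and the adjusted p of camera.

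MOLM-14 cells showed the widest response to R406. The transcript of MYC, a transcription factor that drives growth, fell by 3.38 on the log2 scale, from 3993 ± 135 to 382 ± 16.03 (adjusted p = 2.94e-18). DUSP6, a phosphatase induced by ERK that acts back on ERK, changed by -3.99 ± 0.10 (adjusted p = 1.30e-18). CCNE2, the cyclin E2 of S phase entry, fell from 300.3 ± 10.9 to 8.38 ± 1.25, a change of -5.01 ± 0.10. The replication factor MCM10 changed by -4.89 ± 0.19 and the cytokine gene TNF by -4.31 ± 0.16. Among the genes that rose, SELENOP, a secreted selenium carrier, went from 10.6 ± 2.30 to 421 ± 93.6, a change of 5.18 ± 0.13. Transcripts of the histone genes H2AC6 and H2BC5 rose by 5.60 ± 0.17 and 4.94 ± 0.22. The receptor kinase gene AXL rose by 4.24 ± 0.10, or by 2.39 when the probe sets of the gene were averaged.

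Growth and cell cycle genes fell in MOLM-14 under R406. In the MYC and ribosome biogenesis list, 19 of 22 members fell, 19 adjusted over the list alone (median -2.32, adjusted p = 1.54e-16). Spermidine synthase SRM changed by -2.92 ± 0.059 and the ribosome assembly factor NOP16 by -3.53 ± 0.075. In the DNA replication and E2F list, 24 of 25 members fell, 24 adjusted over the list alone (median -2.81, adjusted p = 8.00e-17, adjusted p = 0.0759 with an estimated correlation and 8.59e-05 without KG-1 R406 replicate 2 as well). UNG, which removes uracil from DNA, changed by -3.02 ± 0.081. The replicative helicase gene MCM7 changed by -2.18 ± 0.080. In the mitosis list, 23 of 23 members fell, 23 adjusted over the list alone (median -1.53, adjusted p = 1.48e-08, adjusted p = 0.272 with an estimated correlation and 0.00181 without KG-1 R406 replicate 2 as well). Cyclin A2, CCNA2, changed by -2.25 ± 0.18 and CDK1 by -1.59 ± 0.14. Among targets and feedback regulators of ERK, 11 of 16 members fell and 1 rose, with 11 that fell adjusted over the list alone (median -1.40, adjusted p = 6.36e-06). SPRY2, an inhibitor of receptor tyrosine kinase signalling, changed by -2.31 ± 0.091. The ACTB 3' to 5' log2 ratio, a measure of RNA integrity, was 0.34 higher in R406 than in DMSO in MOLM-14 (2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The GAPDH ratio differed by 0.078 (exact p = 0.1).

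Biosynthetic and stress response genes fell in MOLM-14 as well. Of the cholesterol biosynthesis genes, 13 of 14 members fell, 13 adjusted over the list alone (median -1.36, adjusted p = 1.06e-07). SQLE, squalene epoxidase, went from 454 ± 12.4 to 23.6 ± 1.24 (-4.21 ± 0.10). In the integrated stress response list of ATF4 targets, 16 of 22 members fell and 3 rose, with 16 that fell adjusted over the list alone (median -0.90, adjusted p = 2.34e-05). Asparagine synthetase ASNS changed by -2.20 ± 0.069 and PSAT1, an enzyme of serine synthesis, by -3.78 ± 0.19. In the unfolded protein response list, 11 of 14 members fell and 1 rose, with 11 that fell adjusted over the list alone (median -1.09, adjusted p = 6.36e-06), and the transcription factor XBP1 changed by -2.45 ± 0.081. In the glycolysis and hypoxia list, 13 of 21 members fell and 4 rose, with 14 that fell adjusted over the list alone (median -0.63, adjusted p = 0.000490, adjusted p = 0.0596 with an estimated correlation and without KG-1 R406 replicate 2), with lactate dehydrogenase LDHA at -1.81 ± 0.078. Of the oxidative phosphorylation genes, 12 of 18 members fell and 3 rose, with 12 that fell adjusted over the list alone (median -0.39, adjusted p = 0.00708, adjusted p = 0.203 with an estimated correlation and 0.0184 without KG-1 R406 replicate 2 as well). Of the primary granule proteins, the enzymes of early myeloid granules, 6 of 9 members fell and 2 rose, with 7 that fell adjusted over the list alone (median -0.63, adjusted p = 0.0261, adjusted p = 0.0596 with an estimated correlation and without KG-1 R406 replicate 2), and proteinase 3, PRTN3, changed by -3.21 ± 0.18.

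Lysosomal, antigen presentation and SYK pathway genes rose in MOLM-14. Of the lysosome genes, 18 of 19 members rose, 18 adjusted over the list alone (median 0.96, adjusted p = 1.48e-08). Prosaposin, PSAP, changed by 1.74 ± 0.062 and the cholesterol transporter NPC2 by 1.60 ± 0.065. In the MHC class II list, 7 of 9 members rose, 7 adjusted over the list alone (median 0.94, adjusted p = 0.00195). HLA-DRA changed by 2.76 ± 0.085 and the invariant chain CD74 by 1.21 ± 0.093. In the SYK and ITAM signalling list, 13 of 17 members rose and 4 fell, with 13 that rose adjusted over the list alone (median 0.48, adjusted p = 0.00713). TYROBP, an adaptor that recruits SYK, changed by 2.90 ± 0.10 and the adaptor BLNK by 3.01 ± 0.11, while SYK itself changed by -0.25 ± 0.065, a call that ended with quantile normalization (-0.14) and with averaged probe sets (-0.10). Of the interferon response genes, 11 of 23 members rose and 2 fell, with 11 that rose adjusted over the list alone (median 0.33, adjusted p = 0.0330), and IRF7 changed by 1.55 ± 0.13. In the integrins and adhesion list, 9 of 15 members rose and 2 fell, with 9 that rose adjusted over the list alone (median 0.66, adjusted p = 0.0443, adjusted p = 0.0660 with an estimated correlation). ITGAL changed by 1.12 ± 0.087 and ITGB2, its partner in the integrin LFA-1, by -0.92 ± 0.062. In the stem and progenitor and HOXA list, 10 of 17 members rose and 2 fell, with 10 that rose adjusted over the list alone (median 0.29, adjusted p = 0.0456, adjusted p = 0.0759 with an estimated correlation), with the receptor KIT at 2.94 ± 0.20 and MEIS1 at 1.03 ± 0.070. No HOXA gene was among the measured members.

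Of 12165 genes tested with limma in MOLM-14, 3787 rose and 3039 fell, 779 and 1102 of them at least 2-fold. The 3 R406 and 3 DMSO arrays did not overlap for 57.7% of genes, against 10% by chance. Quantile normalization ended the calls of the primary granule, stem, interferon and oxidative phosphorylation lists (medians -0.54, 0.19, 0.29 and -0.27), and leaving out the dimmest 33.3% of genes ended those of the primary granule, stem, interferon and integrin lists (-0.63, 0.29, 0.50 and 0.69). The integrin list also lost its call without MOLM-14 R406 replicate 1 (median 0.68), with averaged probe sets (0.25) and with a pseudocount of 16 (0.49), and the stem list without DMSO replicate 1 or R406 replicate 1 or 2 (0.29, 0.30 and 0.21).

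**Figure D1:**
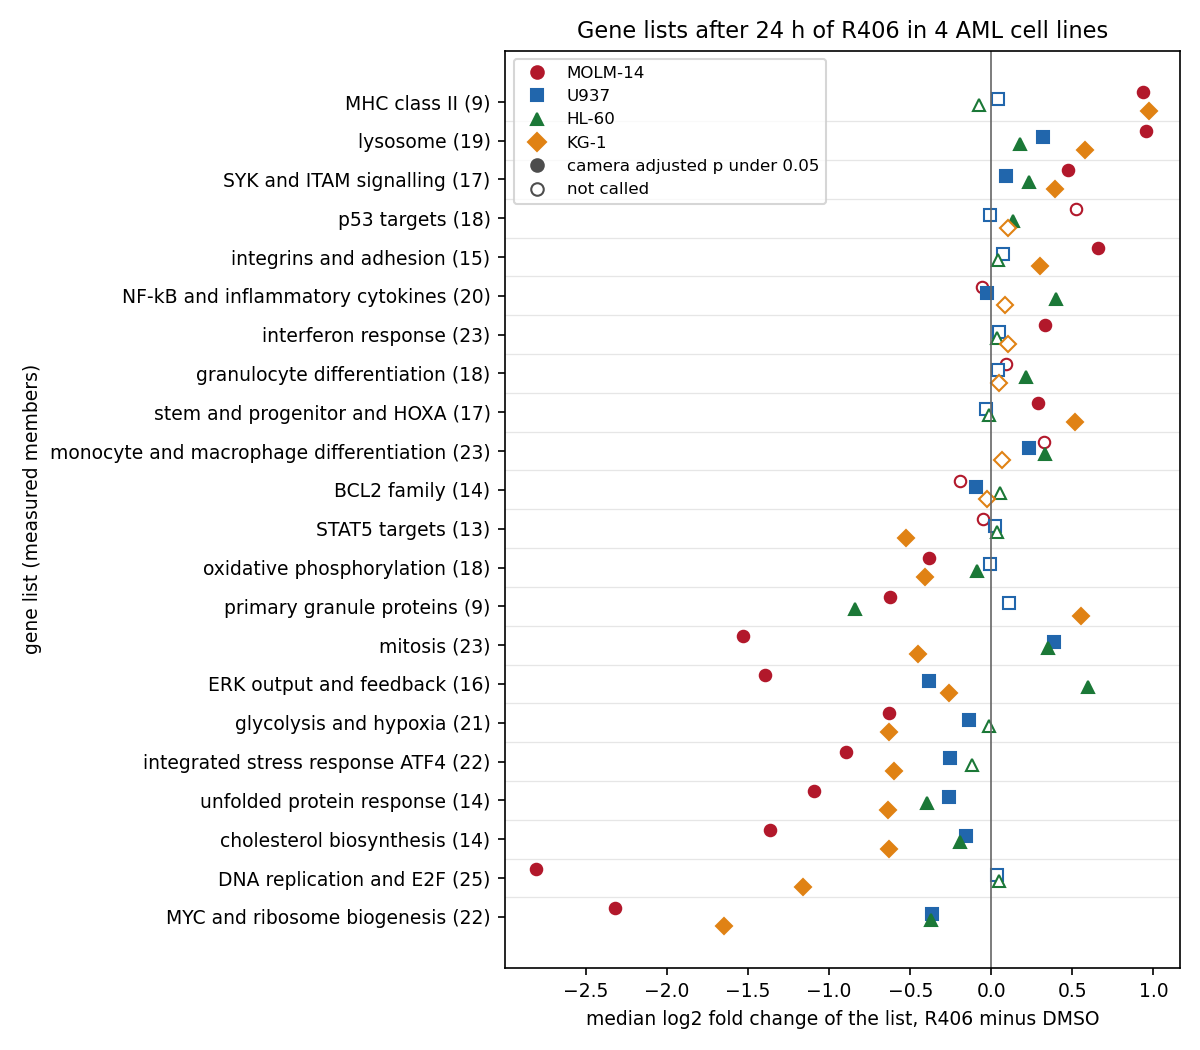
Median log2 fold change (R406 minus DMSO) of each gene list called in at least 1 line, with 1 symbol per cell line and the number of measured members in brackets; filled symbols had a camera adjusted p under 0.05 with the preset correlation. The MYC and ribosome biogenesis list lay below 0 and the lysosome list above 0 in all 4 lines, while the ERK list lay above 0 in HL-60 and below 0 in the other 3 lines.

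U937 cells responded with smaller changes. CCL2, a chemokine that attracts monocytes, fell from 1255 ± 62.3 to 238 ± 17.1, a change of -2.40 ± 0.12 (adjusted p = 3.28e-11). MYC changed by -0.80 ± 0.091 (adjusted p = 4.54e-06), and SLC7A5, a transporter of large amino acids, by -1.04 ± 0.084. RGS16, a regulator of G protein signalling, changed by -1.27 ± 0.14. Heme oxygenase HMOX1 rose from 57.2 ± 5.22 to 149.9 ± 2.17 (1.38 ± 0.14), and the chitinase-like protein CHI3L1 rose by 1.30 ± 0.090. CYP1A1, a target of the aryl hydrocarbon receptor, rose by 1.28 ± 0.18. SYK did not pass the test (0.049 ± 0.065, adjusted p = 0.763).

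Growth and signalling lists were lower in U937. In the MYC and ribosome biogenesis list, 17 of 22 members fell, 21 adjusted over the list alone (median -0.37, adjusted p = 5.08e-20), with NOP16 at -0.49 ± 0.075 and MRTO4, another ribosome assembly factor, at -0.56 ± 0.085. In the ERK output list, 8 of 16 members fell, 9 adjusted over the list alone (median -0.39, adjusted p = 4.06e-08). The ETS factor ETV5 changed by -0.81 ± 0.12 and SPRY2 by -0.52 ± 0.091. EGR1, an immediate early transcription factor, changed by -1.42 ± 0.19, or -0.78 with averaged probe sets. Of the ATF4 targets, 11 of 22 members fell, 11 adjusted over the list alone (median -0.26, adjusted p = 1.67e-09), and ATF4 itself changed by -0.68 ± 0.059. In the glycolysis and hypoxia list, 5 of 21 members fell, 7 adjusted over the list alone (median -0.14, adjusted p = 2.60e-05), with the angiogenic factor VEGFA at -0.71 ± 0.13. Of the NF-kB and inflammatory cytokine genes, 6 of 20 members fell, 6 adjusted over the list alone (median -0.029, mean -0.29, adjusted p = 0.00142). IL1B, the cytokine interleukin 1 beta, changed by -0.79 ± 0.12. In the unfolded protein response list, 5 of 14 members fell, 8 adjusted over the list alone (median -0.26, adjusted p = 1.30e-05, adjusted p = 0.0524 with an estimated correlation and 0.00477 without KG-1 R406 replicate 2 as well). Among cholesterol biosynthesis genes, 3 of 14 members fell, 4 adjusted over the list alone (median -0.16, adjusted p = 0.000552, adjusted p = 0.134 with an estimated correlation), with INSIG1, a brake on sterol synthesis, at -0.80 ± 0.10. In the BCL2 family, which controls cell death, 3 of 14 members fell, 4 adjusted over the list alone (median -0.10, adjusted p = 0.0423, adjusted p = 0.123 with an estimated correlation), and PMAIP1 changed by -0.53 ± 0.10.

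Higher lists in U937 began with the lysosome, where 12 of 19 members rose, 13 adjusted over the list alone (median 0.32, adjusted p = 7.86e-12). NPC2 changed by 0.66 ± 0.065 and hexosaminidase HEXA by 0.60 ± 0.068. In the monocyte and macrophage list, 9 of 23 members rose and 1 fell, with 11 that rose adjusted over the list alone (median 0.23, adjusted p = 3.51e-06). Cathepsin S, CTSS, changed by 0.71 ± 0.083 and the Fc receptor FCGR2B by 0.93 ± 0.14. Among SYK pathway genes, 6 of 17 members rose, 6 adjusted over the list alone (median 0.088, adjusted p = 0.00289), with TYROBP at 0.92 ± 0.10. In the mitosis list, 2 of 23 members rose, 7 adjusted over the list alone (median 0.39, adjusted p = 6.46e-07, adjusted p = 0.342 with an estimated correlation and 0.000338 without KG-1 R406 replicate 2 as well), and the spindle protein ASPM changed by 0.78 ± 0.17.

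The fit called 742 genes higher and 660 lower in U937, 14 and 7 of them at least 2-fold. Genes called higher made up 52.9% of all calls in U937, but 40.8% after median centring. Groups did not overlap for 34.0% of genes, where chance gives 10%. The genes called lower numbered 434 without U937 R406 replicate 1 and 428 without replicate 3. The BCL2 family lost its call without DMSO replicate 2, R406 replicate 2 or R406 replicate 3 (medians -0.071, -0.10 and -0.095), and the mitosis list did with the rotation test fry.

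In HL-60 cells, R406 was followed by higher immediate early and inflammatory transcripts and lower granule enzyme transcripts. EGR1 rose from 48.9 ± 13.0 to 631 ± 91.0, a change of 3.69 ± 0.19 (adjusted p = 7.62e-12). IER3, an early response gene, rose by 2.86 ± 0.11 (adjusted p = 8.99e-14) and IL1B by 1.92 ± 0.12. The monocyte receptor CD14 rose from 279 ± 59.7 to 853 ± 37.0 (1.63 ± 0.13). The granule protease genes PRTN3, CTSG and ELANE changed by -2.36 ± 0.18, -2.04 ± 0.15 and -1.78 ± 0.18. ASS1, an enzyme of arginine synthesis, changed by -2.07 ± 0.074, and IRF8, a transcription factor of monocyte development, by -1.83 ± 0.11. MYC changed by -0.62 ± 0.091 (adjusted p = 3.97e-05), and SYK did not pass the test (-0.030 ± 0.065).

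The lists that rose in HL-60 covered signalling, inflammation and differentiation. In the ERK output list, 11 of 16 members rose, 12 adjusted over the list alone (median 0.60, adjusted p = 2.92e-14). DUSP6 changed by 1.10 ± 0.10 and IER2 by 1.06 ± 0.10. Of the NF-kB and inflammatory cytokine genes, 11 of 20 members rose, 14 adjusted over the list alone (median 0.40, adjusted p = 2.07e-12), with CCL2 at 1.68 ± 0.12. Among granulocyte genes, 6 of 18 members rose and 1 fell, with 9 that rose adjusted over the list alone (median 0.22, adjusted p = 5.17e-05). FPR2, a receptor for formyl peptides, changed by 1.84 ± 0.14 and the neutrophil protein S100A12 by 1.13 ± 0.10. In the monocyte and macrophage list, 10 of 23 members rose and 3 fell, with 12 that rose adjusted over the list alone (median 0.33, adjusted p = 0.000254). Of the lysosome genes, 8 of 19 members rose, 11 adjusted over the list alone (median 0.18, adjusted p = 1.69e-06), with cathepsin D, CTSD, at 0.65 ± 0.089. In the SYK and ITAM list, 9 of 17 members rose and 1 fell, with 9 that rose adjusted over the list alone (median 0.23, adjusted p = 0.00241). The adaptor LCP2 changed by 0.61 ± 0.077 and the kinase FGR by 0.99 ± 0.13. Of the p53 targets, 5 of 18 members rose and 1 fell, with 5 that rose adjusted over the list alone (median 0.14, adjusted p = 0.00592, adjusted p = 0.0533 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 1.12 ± 0.16. In the mitosis list, 2 of 23 members rose, 0 adjusted over the list alone (median 0.35, adjusted p = 6.71e-05, adjusted p = 0.473 with an estimated correlation and 0.00195 without KG-1 R406 replicate 2 as well).

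Lower lists in HL-60 included the primary granule proteins, where 8 of 9 members fell, 9 adjusted over the list alone (median -0.84, adjusted p = 5.49e-13). In the MYC and ribosome biogenesis list, 19 of 22 members fell, 21 adjusted over the list alone (median -0.37, adjusted p = 3.27e-15), with SRM at -0.56 ± 0.059. Of the unfolded protein response genes, 8 of 14 members fell, 11 adjusted over the list alone (median -0.40, adjusted p = 1.92e-06), and the chaperone CALR changed by -0.43 ± 0.082. Among cholesterol biosynthesis genes, 3 of 14 members fell, 5 adjusted over the list alone (median -0.19, adjusted p = 0.00447, adjusted p = 0.201 with an estimated correlation), with SQLE at -0.43 ± 0.10, a call that ended when the 6 HL-60 arrays were fitted alone. Of the oxidative phosphorylation genes, 2 of 18 members fell, 2 adjusted over the list alone (median -0.085, adjusted p = 0.0166, adjusted p = 0.263 with an estimated correlation and 0.0310 without KG-1 R406 replicate 2 as well). The ACTB 3' to 5' log2 ratio differed by -0.13 between R406 and DMSO in HL-60 (exact p = 0.1), and by -0.039 in U937 (exact p = 0.6).

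The fit called 876 genes higher and 971 lower in HL-60, 59 and 35 of them at least 2-fold, and groups did not overlap for 32.8% of genes against 10% by chance. The cholesterol list lost its call without HL-60 DMSO replicate 1 (median -0.13), the oxidative phosphorylation list without DMSO replicate 2 (median -0.072), and the mitosis list with fry.

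R406 lowered growth and ERK feedback transcripts in KG-1 cells. DUSP6 fell from 700.5 ± 76.7 to 47.4 ± 1.15, a change of -3.85 ± 0.10 (adjusted p = 2.00e-17). MYC changed by -2.11 ± 0.091 (adjusted p = 3.43e-14), the ribosome assembly factor NOP16 by -2.76 ± 0.075 and the serine synthesis enzyme PSAT1 by -2.72 ± 0.19. FMO1, a drug-metabolizing monooxygenase, rose from 18.7 ± 2.43 to 563 ± 242, a change of 4.76 ± 0.18. The adhesion receptor gene ADGRG6 rose by 4.57 ± 0.21 and the protease gene PRSS23 by 2.67 ± 0.091. CYP1A1 rose by 2.40 ± 0.18 and the histone gene H2AC6 by 4.86 ± 0.17. SYK rose by 0.39 ± 0.065 and the integrin subunit gene ITGAV by 1.20 ± 0.13.

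KG-1 R406 replicate 2 stood apart from replicates 1 and 3. Its values had an SD of 0.179 from the mean of its group on the log2 scale, against at most 0.161 for the other arrays. With it 2857 genes rose and 2538 fell in KG-1. Without it 2677 rose and 2357 fell, and 4809 genes were called both ways. Leaving it out lowered the correlation that camera estimated for the DNA replication and E2F list from 0.708 to 0.0629 and for the mitosis list from 0.882 to 0.130. These estimates use all lines, so this 1 array also bears on list calls in the other lines. The ACTB 3' to 5' log2 ratio was 0.12 higher in R406 than in DMSO in KG-1, and the GAPDH ratio was 0.10 higher (exact p = 0.1 for each).

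The lists lower in KG-1 again held growth genes. In the MYC and ribosome biogenesis list, 21 of 22 members fell, 21 adjusted over the list alone (median -1.65, adjusted p = 1.02e-20). SRM changed by -2.46 ± 0.059 and BOP1, of ribosome assembly, by -2.68 ± 0.088. In the DNA replication and E2F list, 24 of 25 members fell, 24 adjusted over the list alone (median -1.16, adjusted p = 3.15e-12, adjusted p = 0.138 with an estimated correlation and 0.000691 without KG-1 R406 replicate 2 as well), with the replication licensing gene CDC6 at -2.12 ± 0.18. Of the glycolysis and hypoxia genes, 15 of 21 members fell and 1 rose, with 15 that fell adjusted over the list alone (median -0.63, adjusted p = 1.98e-05), with LDHA at -1.32 ± 0.078. Among cholesterol biosynthesis genes, 10 of 14 members fell, 11 adjusted over the list alone (median -0.63, adjusted p = 2.37e-05, adjusted p = 0.0538 with an estimated correlation and 0.0464 without KG-1 R406 replicate 2 as well), and HMGCS1 changed by -1.65 ± 0.12. Of the ATF4 targets, 16 of 22 members fell and 2 rose, with 16 that fell adjusted over the list alone (median -0.60, adjusted p = 4.89e-05). Of the oxidative phosphorylation genes, 14 of 18 members fell and 1 rose, with 14 that fell adjusted over the list alone (median -0.41, adjusted p = 0.000203, adjusted p = 0.0738 with an estimated correlation and 0.00622 without KG-1 R406 replicate 2 as well), with cytochrome c1, CYC1, at -1.13 ± 0.082. In the ERK output list, 8 of 16 members fell, 9 adjusted over the list alone (median -0.26, adjusted p = 0.000453). Of the STAT5 targets, 10 of 13 members fell and 1 rose, with 10 that fell adjusted over the list alone (median -0.52, adjusted p = 0.00132), with the kinase PIM1 at -1.89 ± 0.10 and the differentiation inhibitor ID1 at -2.56 ± 0.20. In the unfolded protein response list, 9 of 14 members fell and 3 rose, with 9 that fell adjusted over the list alone (median -0.64, adjusted p = 0.00697, adjusted p = 0.201 with an estimated correlation), with the secreted factor MANF at -1.23 ± 0.10. In the mitosis list, 13 of 23 members fell, 13 adjusted over the list alone (median -0.45, adjusted p = 0.00618, adjusted p = 0.598 with an estimated correlation).

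The lists higher in KG-1 were led by the lysosome, where 15 of 19 members rose, 15 adjusted over the list alone (median 0.58, adjusted p = 2.50e-06) and NPC2 changed by 1.28 ± 0.065. In the MHC class II list, 7 of 9 members rose, 8 adjusted over the list alone (median 0.97, adjusted p = 0.000350), with CD74 at 1.10 ± 0.093. In the stem and progenitor and HOXA list, which held no measured HOXA gene, 12 of 17 members rose and 1 fell, with 12 that rose adjusted over the list alone (median 0.52, adjusted p = 0.000859). PBX3, a partner of HOX proteins, changed by 1.13 ± 0.090 and KIT by 2.02 ± 0.20. In the SYK and ITAM list, 13 of 17 members rose and 1 fell, with 13 that rose adjusted over the list alone (median 0.39, adjusted p = 0.00106). TYROBP changed by 1.63 ± 0.10 and the lipid phosphatase INPP5D by 1.05 ± 0.069. In the integrins and adhesion list, 9 of 15 members rose and 2 fell, with 9 that rose adjusted over the list alone (median 0.30, adjusted p = 0.0233), with ITGAL at 1.46 ± 0.087. Of the primary granule proteins, 6 of 9 members rose and 1 fell, with 6 that rose adjusted over the list alone (median 0.55, adjusted p = 0.0168, adjusted p = 0.0728 with an estimated correlation and without KG-1 R406 replicate 2), with MS4A3 at 1.57 ± 0.14 and myeloperoxidase, MPO, at 1.25 ± 0.15. Under DMSO the granule list lay at a median of -4.70 in KG-1 against the mean of the other lines, on the log2 scale. Its rise there thus began from low levels.

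Genes called higher made up 52.96% of the genes called in KG-1, but 44.6% after median centring. In KG-1, 417 genes rose and 534 fell at least 2-fold, and groups did not overlap for 49.7% of genes against 10% by chance. The integrin list lost its call without the dimmest 33.3% of genes (median 0.35) and with averaged probe sets (0.18), and the mitosis list without KG-1 R406 replicate 2 (median -0.10) and with fry.

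Of the 7 lists called in no line and not in the mean with the preset correlation, the aryl hydrocarbon receptor targets had medians of 0.37 in MOLM-14, 0.14 in U937, 0.092 in HL-60 and 0.38 in KG-1 (adjusted p = 0.387, 0.127, 0.125 and 0.519). Of 10 measured targets, 6, 3, 2 and 6 rose in these lines, and 2, 1, 0 and 3 fell. The cytosolic ribosomal proteins had medians of 0.080, -0.022, 0.0070 and 0.091 in that order (adjusted p = 0.340, 0.288, 0.854 and 0.208). The erythroid markers had adjusted p = 0.602, 0.422, 0.544 and 0.677, with medians of 0.17, -0.041, -0.033 and 0.050. For megakaryocyte markers, the medians were 0.19, -0.11, 0.0017 and -0.061, with adjusted p = 0.198, 0.127, 0.606 and 0.677. For B cell markers, the medians were 0.061, -0.040, 0.00061 and 0.065, with adjusted p = 0.718, 0.768, 0.855 and 0.673. For T and NK cell markers, the medians were 0.058, 0.012, -0.027 and 0.14, with adjusted p = 0.387, 0.616, 0.606 and 0.0540. For fibroblast and epithelial markers, the medians were 0.056, -0.032, 0.041 and -0.012, with adjusted p = 0.912, 0.929, 0.883 and 0.572. The T and NK cell list was called in KG-1 with median centring (median 0.074), with a pseudocount of 16 (0.085), without DMSO replicate 2 (0.15), without R406 replicate 2 (0.22) and with fry, and with fry in MOLM-14 too. The rotation test fry, which compares a list with no other genes, also called the aryl hydrocarbon receptor targets in U937 and HL-60 and the ribosomal proteins in MOLM-14, U937 and KG-1. It further called the megakaryocyte markers in MOLM-14 and U937, the B cell markers in MOLM-14 and KG-1 and the fibroblast and epithelial markers in KG-1. For the mean, fry called all of these lists but the erythroid markers. Markers of these other cell types were compared between R406 and DMSO only, so they cannot show other cells present under both. The T cell kinase gene LCK rose in KG-1 by 1.82 ± 0.14.

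The mean effect averages the 4 lines, whether or not they changed the same way. MYC changed by -1.73 ± 0.046 in the mean (adjusted p = 3.95e-18) and passed the test in each line. NOP16 changed by -1.84 ± 0.037, PSAT1 by -2.05 ± 0.10 and SLC7A5 by -1.79 ± 0.042. Among genes with the same sign in all 4 lines, DPEP2, a dipeptidase, rose by 1.98 ± 0.057 and HMOX1 by 1.57 ± 0.070. SAT1, which breaks down polyamines, rose by 1.28 ± 0.029 and the adaptor TYROBP by 1.49 ± 0.048. CCNG2, a cyclin of resting cells, rose by 1.40 ± 0.048. ITGB3, the integrin in the series title, passed the test in no line, with 0.067 ± 0.12 in MOLM-14, -0.0071 ± 0.12 in U937, 0.032 ± 0.12 in HL-60 and 0.17 ± 0.12 in KG-1. Its DMSO intensities were 8.93 ± 0.926, 7.59 ± 1.74, 8.85 ± 0.293 and 7.66 ± 0.434 in that order, near the low end of the arrays.

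For the mean effect, the lists that fell were led by MYC and ribosome biogenesis, where 22 of 22 members fell, 22 adjusted over the list alone (median -1.16, adjusted p = 6.26e-20). In the cholesterol biosynthesis list, 13 of 14 members fell, 13 adjusted over the list alone (median -0.63, adjusted p = 8.81e-08), with SQLE at -1.32 ± 0.051. Of the ATF4 targets, 17 of 22 members fell and 2 rose, with 18 that fell adjusted over the list alone (median -0.44, adjusted p = 5.33e-07), and ASNS changed by -0.94 ± 0.035. Of the unfolded protein response genes, 11 of 14 members fell and 1 rose, with 11 that fell adjusted over the list alone (median -0.56, adjusted p = 7.30e-06). In the glycolysis and hypoxia list, 14 of 21 members fell and 3 rose, with 14 that fell adjusted over the list alone (median -0.42, adjusted p = 2.27e-05). Among ERK output genes, 11 of 16 members fell and 3 rose, with 12 that fell adjusted over the list alone (median -0.38, adjusted p = 0.00111, adjusted p = 0.0527 with an estimated correlation and without KG-1 R406 replicate 2), although the list rose in HL-60 (median 0.60). Of the DNA replication genes, 23 of 25 members fell, 23 adjusted over the list alone (median -1.01, adjusted p = 2.16e-14, adjusted p = 0.0933 with an estimated correlation and 0.000210 without KG-1 R406 replicate 2 as well), with UNG at -1.30 ± 0.040, but this list was not called in U937 (median 0.033) or HL-60 (median 0.050). The mitosis list followed, as 15 of 23 members fell, 15 adjusted over the list alone (median -0.30, adjusted p = 0.00341, adjusted p = 0.539 with an estimated correlation), with medians above 0 in U937 (0.39) and HL-60 (0.35). The calls in those 2 lines ended with fry (adjusted p = 0.0706 and 0.136) and with an estimated correlation (adjusted p = 0.342 and 0.473), but held with that correlation without KG-1 R406 replicate 2 (0.000338 and 0.00195). Of the oxidative phosphorylation genes, 14 of 18 members fell and 2 rose, with 14 that fell adjusted over the list alone (median -0.22, adjusted p = 0.000951, adjusted p = 0.0933 with an estimated correlation and 0.00852 without KG-1 R406 replicate 2 as well). Of the STAT5 targets, 7 of 13 members fell and 1 rose, with 7 that fell adjusted over the list alone (median -0.17, adjusted p = 0.0427, adjusted p = 0.130 with an estimated correlation), with cyclin D2, CCND2, at -1.15 ± 0.039. Among single lines, the STAT5 list was called in KG-1 only.

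All measured lysosome genes rose in the mean, as 19 of 19 members rose, 19 adjusted over the list alone (median 0.49, adjusted p = 7.83e-10). NPC2 changed by 0.93 ± 0.033 and PSAP by 0.79 ± 0.031. In the SYK and ITAM list, 14 of 17 members rose and 1 fell, with 14 that rose adjusted over the list alone (median 0.32, adjusted p = 0.000208). Of the MHC class II genes, 7 of 9 members rose, 7 adjusted over the list alone (median 0.50, adjusted p = 0.00115), with HLA-DMA, which loads peptides, at 1.17 ± 0.049. This list was not called in U937 or HL-60, and HLA-DMA changed by -0.39 in HL-60. In the stem and progenitor list, 9 of 17 members rose, 9 adjusted over the list alone (median 0.14, adjusted p = 0.0237, adjusted p = 0.0558 with an estimated correlation). Of the monocyte and macrophage genes, 11 of 23 members rose and 4 fell, with 12 that rose adjusted over the list alone (median 0.14, adjusted p = 0.0376, adjusted p = 0.0819 with an estimated correlation), with CTSS at 0.76 ± 0.041. Of the interferon genes, 11 of 23 members rose and 3 fell, with 13 that rose adjusted over the list alone (median 0.15, adjusted p = 0.0402, adjusted p = 0.0561 with an estimated correlation), with IRF7 at 1.10 ± 0.066. In the integrins and adhesion list, 8 of 15 members rose and 2 fell, with 9 that rose adjusted over the list alone (median 0.19, adjusted p = 0.0474, adjusted p = 0.0773 with an estimated correlation). Among single lines, the interferon list was called in MOLM-14 only. The stem and integrin lists were called in MOLM-14 and KG-1 only, and the monocyte and macrophage list in U937 and HL-60 only.

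For the mean effect, 3535 genes rose and 2913 fell, and 3502 and 2918 did so without KG-1 R406 replicate 2. The balance turned round for larger changes, with 472 genes higher and 692 lower at a minimum of 1.5-fold, and 69 and 170 at 2-fold. This test uses the spread between arrays within lines, so it speaks of these 4 lines. Called in each line separately, 129 genes rose in all 4, where independent lines would give 3.91, and 218 fell in all 4, where independent lines would give 2.75. In 3 or more lines, 651 rose and 709 fell. The tests of the lines share 1 variance per gene, which can raise such overlaps above those of independent lines. Across genes, which are not independent replicates, the fold changes of MOLM-14 and KG-1 had a Pearson correlation of 0.694 and a Spearman correlation of 0.639, of 6 pairs of lines computed. In both lines 2001 genes rose, against 889 for independent lines, and 1953 fell, against 634. Pearson correlations were 0.391 for U937 and KG-1, 0.383 for MOLM-14 and U937, 0.215 for U937 and HL-60, 0.209 for HL-60 and KG-1, and 0.151 for MOLM-14 and HL-60. The Spearman values of these pairs were 0.338, 0.339, 0.272, 0.227 and 0.198. Quantile normalization ended the call of the interferon list (0.12) and averaged probe sets that of the integrin list (0.10), and leaving out the dimmest 33.3% of genes ended both and the STAT5 call (0.26, 0.19 and -0.18). The STAT5 list also lost its call without MOLM-14 R406 replicate 2 (-0.15) or KG-1 DMSO replicate 1 (-0.18), and the integrin list with a pseudocount of 16 (0.15) or without MOLM-14 DMSO replicate 2 or R406 replicate 1 or 2, U937 DMSO replicate 1 or 3 or R406 replicate 2 or 3, or KG-1 DMSO or R406 replicate 1 (medians from 0.16 to 0.21).

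The lines differed in how they responded, and EGR1 had the widest range of the genes tested. It changed by -3.45 ± 0.19 in MOLM-14, or -2.29 with averaged probe sets, and 3.69 ± 0.19 in HL-60, a range over the lines of 7.14 (adjusted p = 1.53e-14 for the difference between lines). DUSP6 fell in MOLM-14 and KG-1, rose in HL-60 and stood at 0.028 ± 0.10 in U937 (adjusted p = 2.58e-17). TNF fell in MOLM-14 and changed by 1.35 ± 0.16 in HL-60 (adjusted p = 3.78e-14). CCNE2 changed by 0.60 ± 0.10 in HL-60 and -0.58 ± 0.10 in KG-1, beside its fall in MOLM-14 (adjusted p = 4.96e-17). SELENOP, which rose in MOLM-14, stood at 0.036 ± 0.13 in KG-1, and FMO1, which rose in KG-1, stood at 0.20 ± 0.18 in MOLM-14 (adjusted p = 1.11e-15 and 4.83e-13). FLT3, the receptor kinase mutated in MOLM-14, rose in MOLM-14 (1.31 ± 0.14) and KG-1 (1.12 ± 0.14) and fell in HL-60 (-0.94 ± 0.14), with -0.24 ± 0.14 in U937 (adjusted p = 2.17e-09). CYP1A1 rose in U937 and KG-1 and stood at 0.14 ± 0.18 in MOLM-14 and 0.051 ± 0.18 in HL-60 (adjusted p = 7.22e-08). Its intensities in MOLM-14 and HL-60 ran from 9.61 to 16.1, below the array medians. CD14 stood at 0.091 ± 0.13 in MOLM-14, 0.031 ± 0.13 in U937 and 0.16 ± 0.13 in KG-1, against its rise in HL-60 (adjusted p = 1.47e-07). In MOLM-14, U937 and KG-1 its intensities ran from 5.26 to 9.28, near the low end of the arrays. CDKN1A, which rose in HL-60, also rose in MOLM-14 (0.50 ± 0.16), by less than 1.5-fold. It stood at 0.19 ± 0.16 in U937 and 0.31 ± 0.16 in KG-1 (adjusted p = 0.00749 for the difference between lines). The integrin subunit gene ITGAM rose in MOLM-14 (0.51 ± 0.085), U937 (0.76 ± 0.085) and HL-60 (0.71 ± 0.085) and fell in KG-1 (-1.80 ± 0.085; adjusted p = 8.39e-14), where averaged probe sets gave 0.33, 0.49, 0.43 and -0.85.

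Among the lists, the ERK output list was 1.22 (adjusted p = 3.56e-11) higher in HL-60 than in KG-1 by its median difference. The median difference of MOLM-14 minus HL-60 was -1.77 (adjusted p = 7.79e-11), and that of U937 minus HL-60 was -1.001 (adjusted p = 1.92e-26). Primary granule proteins changed differently in HL-60 and KG-1, with a median difference of -1.44 (adjusted p = 2.49e-08). The starting levels were unlike, as the list's DMSO median against the other lines was 1.33 in HL-60 and -4.70 in KG-1. For NF-kB and inflammatory cytokines, U937 minus HL-60 gave -0.38 (adjusted p = 1.06e-15). The mitosis list gave -1.93 (adjusted p = 1.05e-11, adjusted p = 0.171 with an estimated correlation and 0.000543 without KG-1 R406 replicate 2 as well) for MOLM-14 minus U937. Tested for any difference between lines, 6670 genes passed, 54.8% of all, and 884 of these rose in at least 1 line and fell in at least 1 other. Without KG-1 R406 replicate 2 the count was 6697.

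**Figure D2:**
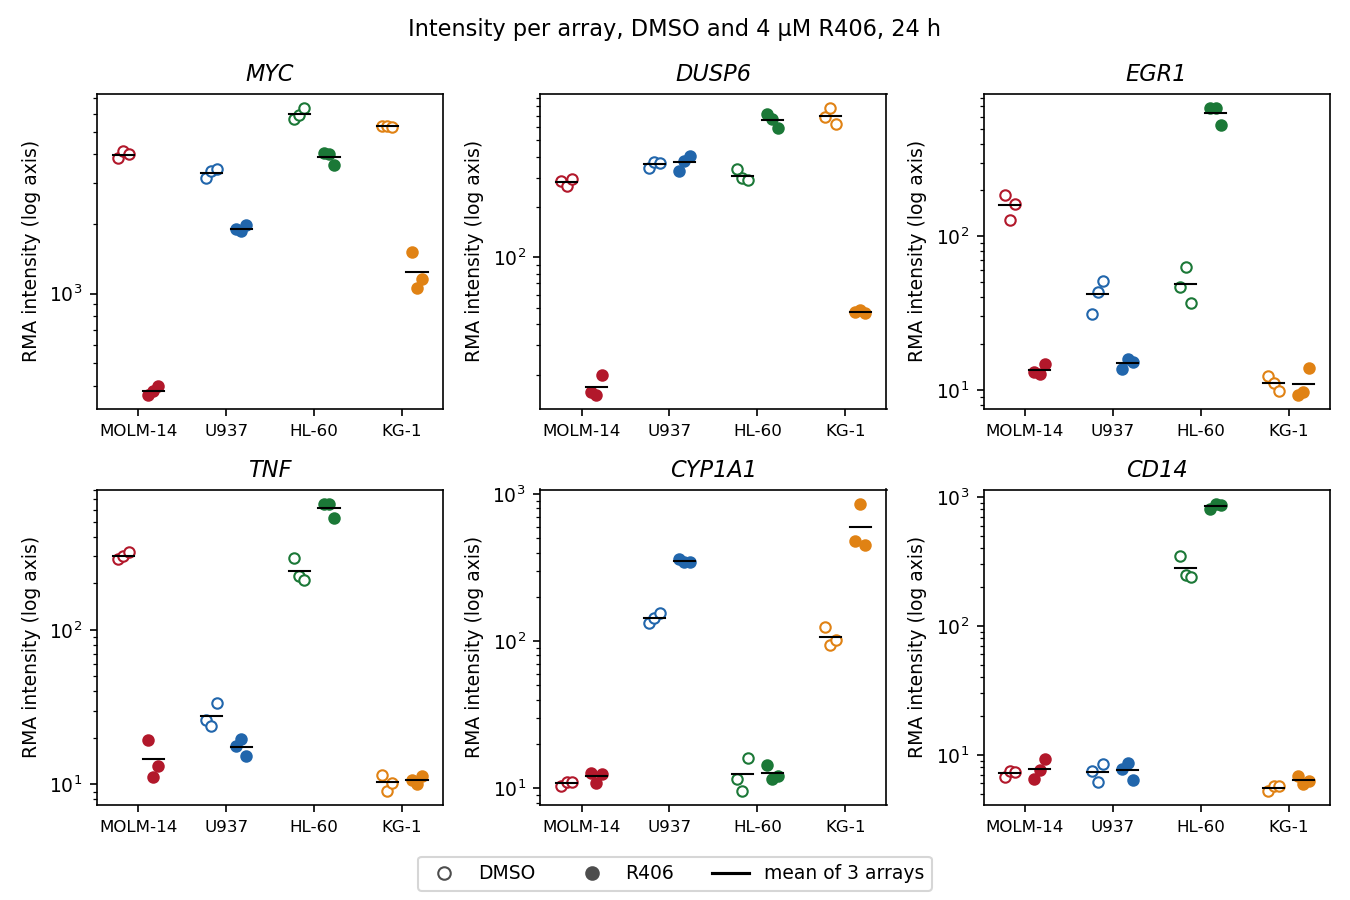
RMA intensity on a log axis of MYC, DUSP6, EGR1, TNF, CYP1A1 and CD14 on each array of the 4 cell lines, with open symbols for DMSO, filled symbols for R406 and a bar at the mean of 3 arrays. The R406 arrays lie below the DMSO arrays for MYC in all 4 lines, and for EGR1 they lie below DMSO in MOLM-14 and above it in HL-60.

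Histone genes, a list chosen after the fold changes were seen, made up a further group. These replication-dependent genes encode the histones that package new DNA. Of 49 measured, 41 rose and 1 fell in MOLM-14 (median 1.24), and 20 rose in KG-1 (median 0.28). In U937 7 rose (median 0.025), and in HL-60 1 fell and 0 rose (median 0.038). The gene that fell in MOLM-14, H4C3, was bright, at 3472 ± 60.6 under DMSO and 2918 ± 106 under R406. The other histone genes had mean intensities of at most 137 in MOLM-14 under DMSO. Some rises there stayed dim, as for H3C1, from 4.81 to 10.0, so the counts speak mostly of dim probe sets. No p is given for the group, because it was chosen for its fold changes in the same data. H2AC6 had a range of 6.02 over the lines (adjusted p = 1.02e-14) and H2BC5 of 5.35 (adjusted p = 2.20e-12). The group was not tested for a difference between lines.

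**Figure D3:**
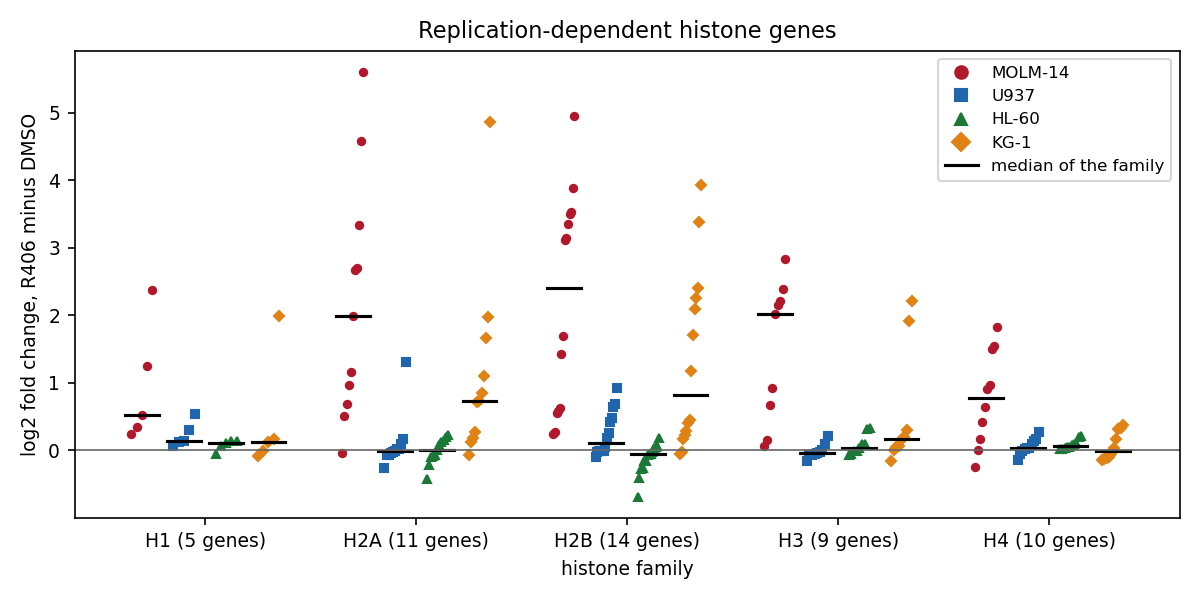
Log2 fold change (R406 minus DMSO) of 49 replication-dependent histone genes by family, with 1 symbol per gene and cell line and a bar at the family median. In MOLM-14 the medians of all 5 families lie above 0, from 0.53 for H1 to 2.40 for H2B.

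Under DMSO alone, the lines carried different lineage markers. Myeloperoxidase, MPO, the main enzyme of primary granules, had an intensity of 6416 ± 114 in HL-60, against 44.0 ± 3.68 in MOLM-14, 10.9 ± 1.03 in U937 and 28.5 ± 3.63 in KG-1 (adjusted p = 1.02e-22 for a difference between lines). The eosinophil granule protein PRG2 and the calcium binding protein S100A8 stood 7.20 and 5.48 above the mean of the other lines in HL-60 on the log2 scale. The class II genes HLA-DPA1 and HLA-DPB1 stood 7.95 and 7.35 above it in KG-1, and HPGDS, a prostaglandin synthase, 7.87. In U937, the glycoprotein GPNMB stood 6.39 above the other lines and CCL2 4.40. In MOLM-14, the cytoskeletal adaptor PDLIM1 and the syndecan SDC2 stood 8.43 and 6.05 above them. By list, the primary granule proteins lay at a median of -4.70 in KG-1 against the mean of the other lines, and all 9 members differed between lines. MHC class II genes lay at 2.92 in KG-1 and -2.33 in U937, with 7 of 9 that differed. Of all genes, 8279 differed between lines under DMSO, 68.1% of those tested.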

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

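In this part, the tests of the ERK list for exchanged labels and array scaling, the RNA integrity and common-shift tests of KG-1 R406 replicate 2, and all tests of the histone genes were chosen only after the result was seen. The results below drew attention because the R406 effect differed between cell lines, or because probe sets outside the comparisons carried a signal.

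The ERK output list rose in HL-60 and fell in the other 3 lines, with median differences of -1.77 for MOLM-14 minus HL-60, -1.001 for U937 minus HL-60 and 1.22 for HL-60 minus KG-1. An exchange of the DMSO and R406 labels in HL-60 would turn the other shared lists round too, but the MYC list had a median of -0.37 in HL-60 (2 SE 0.059). One deviating array is argued against by the lowest median without 1 of the 6 arrays, 0.58 (2 SE 0.49), where camera still called the list. The list's median less that of all genes, 0.60 (2 SE 0.50), restates a camera call that already sets the list against all other genes. A uniform shift from array scaling is argued against by the MYC list, which fell while the ERK list rose. The median of all genes in HL-60, -0.0029, cannot decide this, since the usual steps of RMA hold it near 0. All 13 lists called in HL-60 kept their calls with median centring and with repeated quantile normalization. Median centring moves all genes of an array alike and camera compares a list with the others, so it could hardly end a call. The cause of the rise in HL-60 stays open.

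KG-1 R406 replicate 2 lay further from DMSO than replicates 1 and 3, in 76.8% of the 789 genes called at 2-fold without it. RNA of MOLM-14 R406 cells mixed into the array is argued against, since 14 genes high in MOLM-14 and dim in KG-1 gave a share of -0.0441% (2 SE 0.204), where the 146 genes of the pattern needed 24.6% (2 SE 4.99). Lower RNA integrity cannot be told apart, as the ACTB 3' to 5' log2 ratio lay 0.17 above replicates 1 and 3 and the GAPDH ratio 0.038, while the widest ranges in the other groups were 0.21 and 0.12. A larger shift along the same R406 effect stays open too, with a correlation across genes of 0.293 between the deviation of the array and the effect in the other arrays, short of a clear answer either way. Replicates 1 and 3 enter the deviation and the effect with opposite sign, which pulls this correlation down, so it cannot decide.

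Replication-dependent histone genes rose in MOLM-14. Cross-hybridization within 1 histone family would raise 1 family, but 4 of 5 families had medians above 0 by more than 2 SE, though binding of related transcripts by single probe sets stays open. More cells in DNA replication is argued against by the DNA replication and E2F list, at -2.81 (2 SE 0.46). The histone median less that of all genes, 1.17 (2 SE 0.41), restates the rise for which the list was chosen. A uniform shift from array scaling is argued against by the DNA replication and E2F list, which fell while the histone genes rose. The median of all genes in MOLM-14, 0.068, cannot decide this, since the usual steps of RMA hold it near 0. Scaling that acts on dim genes only was not tested. No other explanation was tested, and the cause stays open.

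The mitosis list differed by -1.93 between MOLM-14 and U937 (adjusted p = 0.171 with an estimated correlation, 0.000543 without KG-1 R406 replicate 2 as well), by -1.88 between MOLM-14 and HL-60 (0.214 and 0.000852), by 0.81 between U937 and KG-1 (0.381 and 0.0257) and by 0.77 between HL-60 and KG-1 (0.395 and 0.0387). Leaving out that array moved the mitosis median in KG-1 from -0.45 to -0.10, so the differences from KG-1 rest in part on it. Primary granule proteins differed by -0.93 for MOLM-14 minus KG-1 and by -1.44 for HL-60 minus KG-1. Under DMSO this list stood far lower in KG-1 (-4.70) than in MOLM-14 (1.27) or HL-60 (1.33), each against the mean of the other lines. NF-kB and inflammatory cytokine genes differed by -0.38 for U937 minus HL-60. The ranges of log2 fold change over the lines were 7.14 for EGR1, 6.02 for H2AC6, 5.66 for TNF, 5.61 for CCNE2, 5.35 for H2BC5 and 5.26 for SELENOP. For DUSP6 the range was 5.09, for FMO1 4.82, for HES1 4.80 (its change in MOLM-14 was 3.81, or 1.01 with averaged probe sets), for MCM10 4.80, for ADGRG6 4.66 and for H2AC17 4.65. The lists called as different numbered 15 between MOLM-14 and U937, 13 between MOLM-14 and HL-60, 8 between MOLM-14 and KG-1, 10 between U937 and HL-60, 10 between U937 and KG-1 and 15 between HL-60 and KG-1. With an estimated correlation 2, 8, 2, 5, 2 and 6 of these calls held, and 13, 13, 6, 6, 5 and 12 without KG-1 R406 replicate 2 as well. Of 103 genes that the naming rule took for the R406 comparisons, 102 differed between lines, against 54.8% of all genes, but the rule favours such genes by its construction. Of 1923 probe sets with no gene name here, 719 (37.4%) were called for the mean effect.

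Other splits of the arrays were fitted as well. For 1 line, 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real grouping called 6826 genes in MOLM-14, 1402 in U937, 1847 in HL-60 and 5395 in KG-1, and the highest other split called 1, 1, 1 and 6. For the mean effect, 1 of 100 splits, the real one, reached 6448 genes and the highest other called 5721. For the difference between lines these numbers were 1 of 100, 6670 and 5815, and for the DMSO groups 1 of 100, 8279 and 3621. The highest splits of the mean and of the difference kept or mirrored the real grouping in 2 lines, and the 72 splits that kept it in no line called 0 genes. Splits that mix R406 and DMSO arrays also raise the shared variance, which lowers their counts. The real split is itself counted, so 1 of 100 is the smallest share possible. Because the arrays of a group may share a culture, these splits cannot exclude chance between cultures.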

How the results depend on the processing

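Leave-outs for the count of genes called the same way in all 4 lines, and an estimated correlation with KG-1 R406 replicate 2 left out, were chosen after the results were seen. Asking for at least 1.5-fold left 3612 genes in MOLM-14, 215 in U937, 383 in HL-60, 2594 in KG-1 and 1164 for the mean, since small changes no longer count. With an estimated correlation 9 lists were called for the mean in place of 17, and 10 without KG-1 R406 replicate 2 as well. Leaving out that array too, lists called went from 11 to 12 in MOLM-14, 8 to 10 in U937, 9 to 12 in HL-60 and 11 to 14 in KG-1. Among other changes, it brought back DNA replication calls in MOLM-14, KG-1 and the mean and mitosis calls in MOLM-14, U937 and HL-60, and ended the glycolysis call in MOLM-14, the granule calls in MOLM-14 and KG-1 and the ERK call in the mean. The rotation test fry, which compares a list with no other genes, called 26 lists in MOLM-14 and 28 for the mean. With averaged probe sets RPS14 reversed, to -0.14 in MOLM-14, -0.10 in KG-1 and -0.059 in the mean. The cause was not tested. Averaged probe sets moved 74 called values of named genes by more than 1.5 times and a pseudocount of 16 moved 64.

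Of the other comparisons of a main count with an alternative, 257 stayed within 1.5 times. Named genes kept direction and side of the threshold 13060 times, lost the call 334 times and gained it 86 times, and gene lists 2530, 86 and 66 times. Median centring lowered the share of called genes that rose from 52.9% to 40.8% in U937 and from 52.96% to 44.6% in KG-1. Leaving out 1 array gave 6360 to 6670 genes in MOLM-14, 935 to 1025 in U937, 1396 to 1524 in HL-60, 5034 to 5331 in KG-1 and 6303 to 6519 for the mean. Genes that fell in U937 numbered 434 without R406 replicate 1 and 428 without replicate 3. Leave-outs also gave 6407 to 6753 for the difference between lines, 8087 to 8204 for the DMSO groups and 261 to 426 genes called the same way in all 4 lines. Lists called ran from 14 to 16 in MOLM-14, 11 to 13 in U937, 12 to 14 in HL-60, 16 to 17 in KG-1 and 15 to 18 for the mean. The Pearson correlations ranged from 0.686 to 0.725 for MOLM-14 and KG-1 over the alternatives, and from 0.148 to 0.174 for MOLM-14 and HL-60. A block for the replicate number called 6725, 1192, 1655 and 5360 genes, and 6386 for the mean. After removal of group means, arrays of a line with the same replicate number correlated by -0.084 to 0.071 and others by -0.13 to 0.15. In U937 alone these ranges were -0.0046 to 0.033 and -0.033 to 0.013. The values gave no clear sign of a pairing by number, but 3 arrays a group cannot exclude it. Signal over background was not tested here, and genes near the lowest intensities have compressed fold changes.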

Other observations

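Counts of histone genes by family come from a list chosen only after the fold changes were seen, and no difference between families was tested. In MOLM-14, 13 of 14 H2B genes rose (median 2.40), 10 of 11 H2A genes (median 1.99), 7 of 9 H3 genes (median 2.02), 7 of 10 H4 genes (median 0.78) and 4 of 5 H1 genes (median 0.53). H4C3, the brightest of the measured histone genes in MOLM-14, fell by 0.25 there on the log2 scale. In KG-1, 9 H2B genes (median 0.82) and 7 H2A genes (median 0.73) rose, against 2 H3 genes (median 0.17) and 1 H4 gene (median -0.0090). H2BC8 changed by 3.12 ± 0.12 in MOLM-14 and stood at 0.28 ± 0.12 in KG-1, which did not pass the test there (adjusted p = 4.72e-13 for a difference between lines). In U937, 4 H2B genes, 2 H1 genes and 1 H2A gene rose. In HL-60 the 1 histone gene that passed, H2BC12, fell by 0.69, against a rise of 3.88 ± 0.11 in MOLM-14.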
